A study of Mus with 8 samples.

How the data were processed

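RNA was measured in 8 libraries of mouse bone-marrow monocytes, which are precursors of macrophages and dendritic cells. Per the labels' protocols, the cells were isolated by negative selection, encapsulated in stiff hydrogels and cultured to day 3 with GM-CSF (100 ng/mL), IL4 (200 ng/mL) and PGE2 (100 ng/mL). The hydrogels were then digested with collagenase and alginate lyase, and libraries were made with an mRNA kit. The deposited values are whole counts per Ensembl gene ID, not normalized, in a series table of 17640 IDs and in 8 per-library files. All 8 per-library files were checked and held the same values as the series table. Per the submitters' processing notes, Salmon, DESeq2 and the mouse build GRCm38 were used; the notes give no versions or order. How transcript estimates were summed to genes, rounded and filtered, and whether strand was used, is not given in the sources used here. The smallest sum of an ID over the 8 libraries was 10, so the table looks filtered on that sum. Salmon divides reads that match several transcripts by estimation, so counts of near-identical or overlapping genes are uncertain, and without names these IDs were not marked.

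The files do not pair gene IDs with names. The gene table used as a reference (49997 genes) held an Ensembl ID for 0 of them, so 0 of the 17640 IDs were matched to a symbol. For this reason 34 gene lists chosen before the data were examined, among them dendritic cell, monocyte, macrophage, inflammatory, JAK-STAT, matrix and cell-type marker lists, were not tested. The levels of Jak2 and Pik3cg were not analysed here. The rule for named genes, also fixed in advance, took the IDs with the smallest p where fewer than 5 passed the threshold. Because the IDs carry no names, only 2 higher and 2 lower IDs are printed. They are the first 2 by p in the matrix comparison averaged over genotypes and the first 2 by p in the summed genotype comparison.

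Libraries were assigned to 4 groups of 2 from the labels: control (Vav-iCre) or Jak2 V617F cells, in viscous or elastic matrix. Titles end in a number that 1 viscous and 1 elastic library of a genotype share. The control numbers are called W1 and W2 here, and the Jak2 V617F numbers J1 and J2. The labels do not say whether a number marks an animal, a culture or a day. The p-values therefore measure the spread between these libraries, which may be partly technical. No replicate pair agreed within counting noise (chi-square per degree of freedom 19.4 to 264.9), so none was treated as a second deposit of the same library; this does not show that libraries are independent samples.

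Counts were analysed with edgeR 4.0.16 in R 4.3.3. IDs were kept with filterByExpr by group (14785 IDs, holding at least 99.96% of the counts of every library), and libraries were scaled by TMM. A quasi-likelihood model with 4 group means was fitted to all 8 libraries, which share 1 estimate of the spread per gene. Contrasts were elastic against viscous averaged over genotypes and within each genotype, the difference of the matrix effects, and Jak2 V617F against control within each matrix. A genotype comparison over both matrices used the counts summed per title number (2 sums against 2). Tests were two-sided, and an ID was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were derived from the test statistic. CPM are counts divided by the TMM-scaled library total in units of 1e+06 counts, and log2 CPM used a prior count of 2. The 95% intervals use the model's degrees of freedom.

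Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile scaling, no filter, a filter of at least 50 counts in 2 or more libraries, DESeq2 1.42.0 (Wald test), limma-voom (limma 3.58.1), an absolute log2 fold change of 1 or more, an adjusted p under 0.01, each library left out, the title number as a block, a fit of only the 4 libraries compared, and the genotype effect averaged over 8 libraries. Leaving out both W1 libraries, leaving out each sum or each library for the correlation, and voom with library quality weights were added after seeing the data. The counts of shared direction between the genotypes and their reference splits were added then too. Adjusted p-values that DESeq2 left undefined (860 IDs in the control matrix contrast and 287 in the elastic genotype contrast) were counted as not called. A list of 55 IDs was taken from the cell cycle training pairs of scran 1.30.0 and tested with camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

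The tests were checked on 5 simulated data sets with 200 changed genes each, 100 at 2-fold and 100 at 4-fold. For the averaged matrix contrast (14504 genes), edgeR recovered 50.8% of the 2-fold and 90.4% of the 4-fold changes, and 6.24% of its calls were false. DESeq2 recovered 77.6% and 97.0%, and 28.1% of its calls were false. For the control matrix contrast (14506 genes), edgeR recovered 10.2% and 77.6% with 6.79% false calls, against 41.8% and 90.4% with 32.8% false calls for DESeq2. For the genotype contrast in viscous matrix (14494 genes), edgeR recovered 9.40% and 73.6% with 6.53% false calls, against 41.6% and 91.8% with 33.2% for DESeq2. Apart from the set changes, the simulated libraries were drawn independently around a common mean per gene. They lack any structure shared by libraries of the same title number, so these rates may not hold for the real counts. The recovered shares also depend on the 200 changed genes set in each data set. With fewer changed genes, the Benjamini-Hochberg adjustment is stricter for a single gene. How many 2-fold or 4-fold changes the real comparisons would miss can therefore not be read from these shares. DESeq2 counts below are given as those of a test that was more permissive in these simulations. Library totals of 30632355 to 38408851 counts leave the spread between libraries, rather than counting noise, as the main limit for all but low-count IDs.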

Results

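Monocytes from the bone marrow of control mice and of mice carrying the Jak2 V617F mutation, a driver of myeloproliferative neoplasm, were grown for 3 days in stiff hydrogels that were either viscous or elastic. The design asks how matrix elasticity changes the transcripts of these cells, and whether the Jak2 mutation alters that response. Titles mark the viscous gels as VLVG and the elastic gels as NbTz. A matrix effect here is a difference between these gels, and elasticity cannot be told apart from any other difference between them. Each of the 4 groups held 2 libraries. Totals were 32605711 and 35011427 counts for control cells in viscous matrix (W2 and W1), and 33047053 and 30632355 for control cells in elastic matrix (W2 and W1). Jak2 V617F libraries held 38408851 and 36532492 counts in viscous matrix (J1 and J2), and 35007587 and 31713975 in elastic matrix (J1 and J2). Between 16350 and 16827 gene IDs had at least 1 count in a library.

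The first principal component set 1 pair of control libraries apart, and the second ordered the libraries by matrix. The first principal component of log2 CPM held 41.5% of the variance and set both W1 libraries (scores 78.2 in viscous and 69.4 in elastic matrix) apart from the other 6 (−37.1 to −10.9). On the second component (15.3%), the 4 elastic libraries scored 10.7 to 34.2 and the 4 viscous libraries −47.7 to 5.29, without overlap. For any 1 measure, chance separates 4 against 4 in this way in 2.86% of orders, but this component was not set beforehand as the measure. The step between the matrices (5.29 to 10.7) was smaller than the step from −17.7 (W1) to 5.29 (J1) within viscous matrix. Replicates were closest in Jak2 V617F cells in elastic matrix, with a root mean square difference of 0.56 log2 CPM. They were farthest apart in the control groups, at 0.96 in viscous and 0.97 in elastic matrix.

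**Figure D1:**
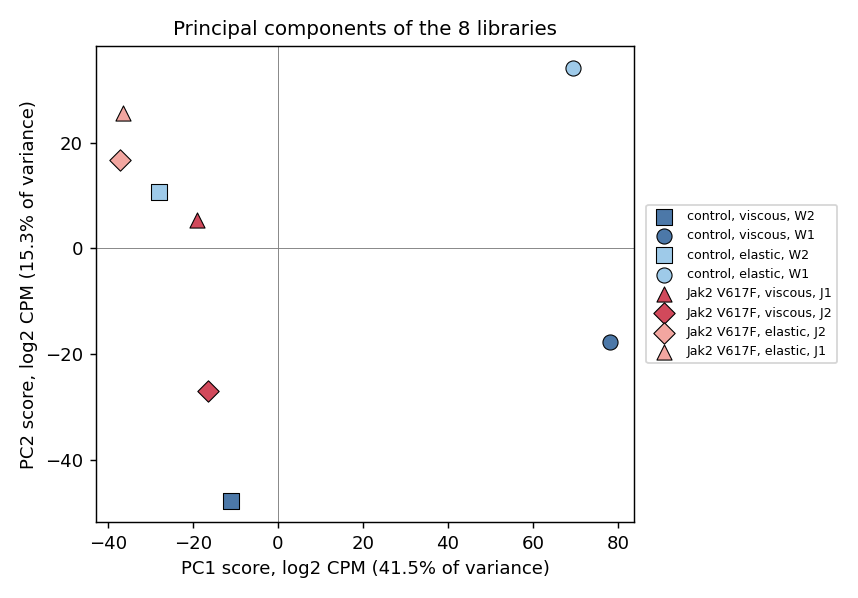
Scores of the 8 libraries on the first 2 principal components of log2 CPM, with the share of variance on each axis; each point is 1 library, colours mark the group and symbols the title number. Both W1 libraries lie at 69.4 and 78.2 on the first axis, and all 4 elastic libraries lie above the 4 viscous ones on the second.

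Elastic and viscous matrix were compared first over both genotypes. The IDs with the smallest p, ENSMUSG00000022504 and ENSMUSG00000060586, were both lower in elastic matrix, with all 4 viscous libraries above all 4 elastic ones. ENSMUSG00000022504 stood at 42.9 ± 1.49 CPM (SD, n = 2) in viscous and 10.5 ± 1.26 CPM in elastic matrix in control cells, and at 23.8 ± 3.84 and 7.82 ± 1.05 CPM in Jak2 V617F cells. ENSMUSG00000060586 stood at 159.7 ± 34.7 and 43.6 ± 4.28 CPM in control cells, and at 130.5 ± 26.1 and 48.6 ± 1.16 CPM in Jak2 V617F cells (SD, n = 2 in each group). Averaged over genotypes, the log2 fold changes were −1.82 (SE 0.13) and −1.65 (SE 0.15), or 3.52-fold and 3.14-fold lower. Neither passed the edgeR test, with adjusted p = 0.0548 and 0.123. Under DESeq2 they were called, with adjusted p = 3.23e-25 and 6.32e-18. Over 18 alternative settings the adjusted p ranged from these DESeq2 values to 0.73 and 1, and was under 0.05 in 5 and 3 settings. For ENSMUSG00000022504 these included both other low-count filters (0.045 without a filter and 0.0487 with the stricter one); besides DESeq2, the others for both IDs were the 2 fits with the title number as a block, given with the alternatives. The log2 fold changes stayed between −1.89 and −1.73 and between −1.75 and −1.53. Of 14785 IDs, edgeR called 0 in the main fit, against 5 with the title number as a fixed block. The main fit gave 928 IDs an unadjusted p under 0.05 (429 higher and 499 lower in elastic matrix), where 739 would do so by chance. The excess was not stable with 1 library left out: in 3 of the 8 cases the count was below the number expected by chance. Each such fit leaves 1 library in a group and changes the spread shared by all groups. The changes therefore do not show that the effect rests on any single library. limma-voom also called 0 (925 at unadjusted p under 0.05), and DESeq2 called 134 (67 higher and 67 lower). Without the W1 libraries, edgeR called 2 IDs, both higher, and DESeq2 called 345, of which 95 were among its 134.

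**Figure D2:**
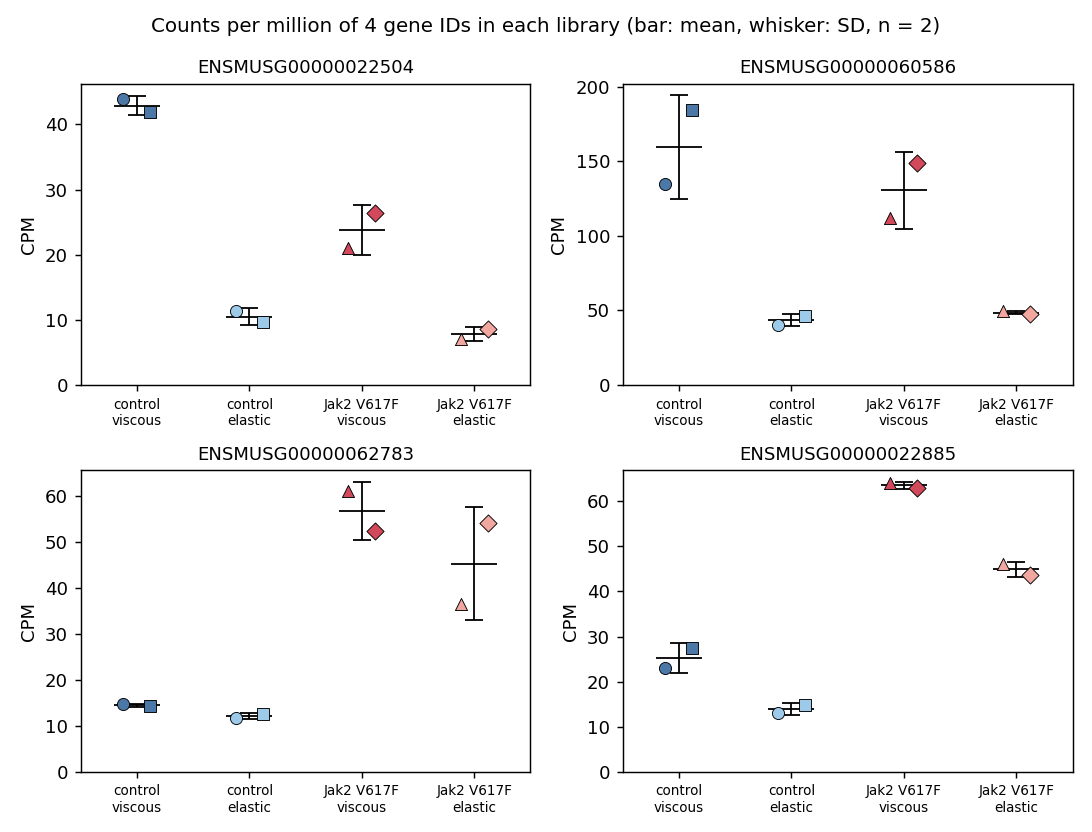
CPM of the 4 named gene IDs by group; each point is 1 library (symbols mark the title number), the horizontal bar is the mean and the whisker the SD of 2 libraries. In the upper panels the elastic libraries lie at 7.08 to 11.4 and 40.5 to 49.4 CPM, below every viscous library; in the lower panels every Jak2 V617F library lies above every control library.

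In control cells alone, the same IDs led the list. ENSMUSG00000022504 was 4.08-fold lower in elastic matrix (log2 fold change −2.03, SE 0.18) and ENSMUSG00000060586 was 3.67-fold lower (−1.87, SE 0.21). By edgeR their adjusted p-values were 0.25 and 0.497. limma-voom with the title number as a random block called ENSMUSG00000022504 (adjusted p = 0.0337). edgeR called 0 of 14785 IDs, with 717 at unadjusted p under 0.05, where 739 would do so by chance. limma-voom called 0, with 709 at that level. The 717 became 495 to 1212 with 1 library left out and 287 on the 4 control libraries alone. DESeq2 called 35, 23 of them higher and 12 lower in elastic matrix, both named IDs included. Without the W1 libraries, DESeq2 called 104 IDs, 16 of them shared with the 35, and edgeR called 0. This leaves 1 control library in each matrix, so the spread in these fits comes only from the Jak2 V617F groups, whose replicates lay closer together, and the 104 say nothing of the spread in control cells.

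In Jak2 V617F cells, ENSMUSG00000022504 was 3.04-fold lower in elastic matrix (log2 fold change −1.60, SE 0.18) and ENSMUSG00000060586 was 2.68-fold lower (−1.42, SE 0.21). By edgeR both had an adjusted p of 0.93. edgeR called 0 of 14785 IDs, with 455 at unadjusted p under 0.05 (222 to 576 with 1 library left out); limma-voom called 0, with 457. DESeq2 called 35, of which 20 were higher and 15 lower, again with both named IDs. Replicates lay closer together in these groups than in the control groups, and all 8 libraries share the spread in these fits. Without the W1 libraries DESeq2 called 189 IDs, including 33 of the 35, and edgeR called 1, higher in elastic matrix, with 1217 at unadjusted p under 0.05. edgeR on the 4 Jak2 V617F libraries alone also called 1, higher in elastic matrix, with 1194 at that level. The order of the genotypes in these counts thus depends on the fit: 717 in control and 455 in Jak2 V617F cells with a shared spread, but 287 and 1194 with each fitted alone. Both counts with a shared spread were below the 739 expected by chance.

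Over all 14785 IDs, 59.5% had a matrix effect of the same sign in control and Jak2 V617F cells, and 60.6% of the 11743 IDs with a mean of at least 50 counts. Among IDs picked by p in both genotypes the same direction was more frequent. Of the IDs with an unadjusted edgeR p under 0.05 in both genotypes, 141 differed in the same direction (63 higher and 78 lower in elastic matrix) and 9 in opposite directions. Independent lists of these sizes would share 11.1 and 10.95. With each genotype fitted alone, so that no spread was shared, the counts were 92 in the same and 1 in opposite directions, against 10.8 and 10.3 by chance. In that fit 98.9% of the 93 shared IDs thus had the same direction. Over the other 8 pairings of splits of each genotype's libraries into 2 and 2, the more frequent direction held 52.9% to 85.5%. Where the control libraries were split by number, these pairings shared 55 to 458 IDs. The rest shared only 4 to 8, so their percentages are imprecise. DESeq2 called 16 IDs in both genotypes, 10 higher and 6 lower in elastic matrix, and 0 in opposite directions (0.043 and 0.040 by chance). With each genotype fitted alone, it called 16 of 13736 IDs in control and 235 in Jak2 V617F cells. Of these 8 were shared in the same direction, 3 higher and 5 lower, and 0 in opposite directions (0.135 and 0.138 by chance). Across genes, which are not independent replicates, the log2 fold changes of the genotypes correlated with r = 0.25 and rho = 0.26 over 14785 IDs, and with r = 0.43 and rho = 0.32 over the 11743 IDs with a mean of at least 50 counts. The other 8 pairings gave an absolute r of 0.011 to 0.35 over the latter IDs. The r over all IDs was 0.129 without W1 in viscous matrix and 0.075 without W2 in elastic matrix.

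**Figure D3:**
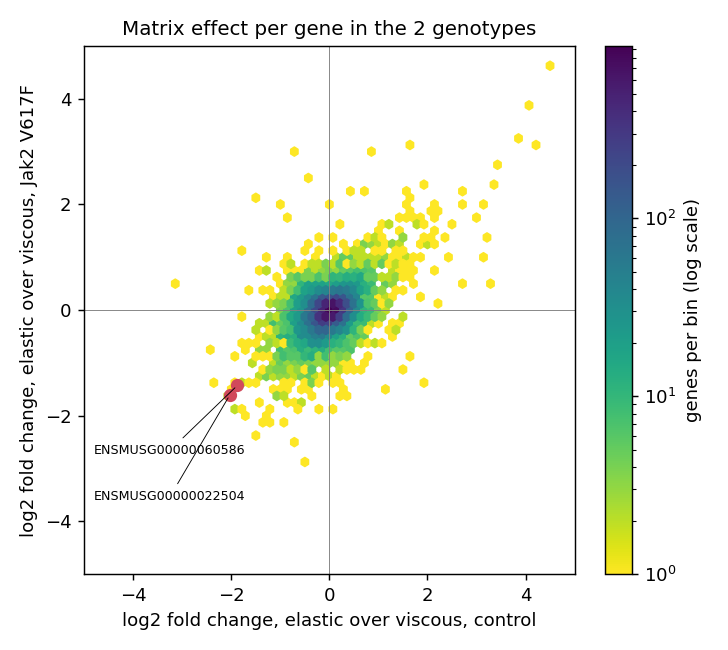
Log2 fold change of elastic over viscous matrix in control cells (horizontal) and Jak2 V617F cells (vertical) for 11743 gene IDs with a mean of at least 50 counts, as hexagonal bins coloured by the number of genes on a log scale; 11 IDs lie outside the axes. Red points mark the named matrix IDs, which lie in the lower left; r across genes was 0.43.

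The difference between the 2 matrix effects tests whether the mutation alters the response to elastic against viscous matrix. For ENSMUSG00000022504 the log2 fold change in Jak2 V617F cells minus that in control cells was 0.42 (SE 0.25, 95% interval −0.18 to 1.02). For ENSMUSG00000060586 the difference was 0.45 (SE 0.29, 95% interval −0.24 to 1.14), and both edgeR adjusted p-values were 1. In this model, which pools the spread of all groups and ignores the title number, both intervals include 0. They also do not exclude a difference of 1 log2 unit. edgeR called 0 of 14785 IDs, with 254 at unadjusted p under 0.05 (87 to 695 with 1 library left out), fewer than the 739 expected by chance; limma-voom called 0, with 259. DESeq2 called 2, both with a lower elastic effect in Jak2 V617F cells, and without the W1 libraries it called 8, which included 0 of these 2.

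Genotypes were then compared within each matrix. In viscous matrix, ENSMUSG00000062783 stood at 56.8 ± 6.28 CPM (SD, n = 2) in Jak2 V617F and 14.5 ± 0.31 CPM in control cells, 3.91-fold higher (log2 fold change 1.97, SE 0.21). ENSMUSG00000022885 stood at 63.5 ± 0.77 and 25.2 ± 3.24 CPM, 2.52-fold higher (1.33, SE 0.14). Both had an edgeR adjusted p of 0.31, and DESeq2 called both. edgeR called 0 of 14785 IDs, with 1081 at unadjusted p under 0.05 (506 to 1929 with 1 library left out); limma-voom called 0, with 1125. DESeq2 called 61, of which 35 were higher and 26 lower in Jak2 V617F cells. Without the W1 libraries, which stand apart from the other control pair, DESeq2 called 170, of which 29 were among the 61, and edgeR called 0, again with the spread of the Jak2 V617F groups only.

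In elastic matrix the same IDs led. ENSMUSG00000062783 stood at 45.3 ± 12.4 CPM (SD, n = 2) in Jak2 V617F and 12.1 ± 0.63 CPM in control cells, 3.74-fold higher (log2 fold change 1.90, SE 0.21). ENSMUSG00000022885 stood at 44.9 ± 1.68 and 13.9 ± 1.28 CPM, 3.23-fold higher (1.69, SE 0.14). Their edgeR adjusted p-values were 0.392 and 0.138, and DESeq2 called both. edgeR called 0 of 14785 IDs, with 654 at unadjusted p under 0.05. This was below the 739 expected by chance, whereas the 1081 in viscous matrix exceeded it. limma-voom called 0, with 561, and DESeq2 called 44 (26 higher and 18 lower). The 654 became 309 without W1, 2344 without W2 and 236 without J2 in elastic matrix. Without the W1 libraries DESeq2 called 58, of which 19 were among the 44, with the same limit.

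Over both matrices, all 4 Jak2 V617F libraries lay above all 4 control libraries for both of these IDs. On counts summed per title number, ENSMUSG00000062783 was 3.87-fold higher (log2 fold change 1.95, SE 0.11) and ENSMUSG00000022885 was 2.79-fold higher (1.48, SE 0.12). Their edgeR adjusted p-values in this comparison of 2 sums against 2 were 0.446 and 0.792. edgeR called 0 of 15239 IDs, with 795 at unadjusted p under 0.05 (162 to 5157 with 1 sum left out); limma-voom called 0, with 768, and DESeq2 called 106 (57 higher and 49 lower). When the effect was instead averaged over the 8 libraries, edgeR called these 2 IDs, with log2 fold changes of 1.51 (SE 0.097, adjusted p = 0.0296) for ENSMUSG00000022885 and 1.94 (SE 0.15, adjusted p = 0.040) for ENSMUSG00000062783. DESeq2 called 336 IDs in this averaged comparison (153 higher and 183 lower). Both of these fits treat libraries of the same title number as independent. The summed count also depends on which control number is kept: it was 0 without W1, J1 or J2, and 2664 without W2, when W1 alone stood for control cells.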

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

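Leaving out both W1 libraries, leaving out each sum, leaving out each library for the correlation, and library quality weights were chosen only after the data were seen. The 0 calls of edgeR held in 105 of 122 alternative counts of calls, among them both other scalings, limma-voom with and without quality weights, and each single library left out of the 6 contrasts, where a lone library is assumed to vary like the other groups. Stricter thresholds (14 more counts) cannot add a call to 0. The fits with 1 library left out hold fewer libraries, so 0 calls in them add little. DESeq2 called more in every comparison: 134 for matrix over both genotypes, 35 in control, 35 in Jak2 V617F cells, 2 for the difference of matrix effects, 61 for genotype in viscous, 44 in elastic matrix and 106 for summed counts; in the 3 simulated comparisons 28.1% to 33.2% of its calls were false. For matrix over both genotypes edgeR called 1 ID without a low-count filter, 1 with the stricter filter and 2 without both W1 libraries. For matrix in Jak2 V617F cells it called 1 on only the 4 libraries compared and 1 without both W1 libraries. The summed genotype count was 2 as the average over 8 libraries, and 0 to 2664 with 1 sum left out. The correlation of matrix effects over all IDs was 0.25, and 0.075 to 0.28 with 1 library left out; over IDs with at least 50 counts it was 0.43. Other causes were not tested. The 4 named IDs kept their direction in all 244 alternative values, and 23 of these passed the threshold that the original values missed. These IDs were picked by small p in the same libraries, and their values did not overlap between the sides compared. Their direction could therefore hardly reverse, so keeping it adds no support, and their fold changes may be too large. Another scaling moved the median log2 fold change of all IDs by at most 0.022.

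With the title number as a fixed block, edgeR called 5 IDs for matrix over both genotypes (1 higher and 4 lower, among the latter ENSMUSG00000022504 with adjusted p = 0.0279 and ENSMUSG00000060586 with 0.0406) and 0 in the other 3 matrix contrasts. As a random block (correlation 0.38) limma-voom called these 2 IDs over both genotypes (adjusted p = 0.00948 and 0.0147). In control cells it called 1, ENSMUSG00000022504 (adjusted p = 0.0337), and elsewhere it called 0. IDs at unadjusted p under 0.05 rose from 928 to 1757 (fixed) and 1665 (random) over both genotypes, from 717 to 1397 and 1391 in control cells, from 455 to 1036 and 890 in Jak2 V617F cells, and from 254 to 531 and 587 for the difference. Deviations from group means of libraries with the same number correlated at 0.53 in control and −0.089 in Jak2 V617F cells, and the labels do not state what the number marks. The number was therefore not taken as a pairing in the main comparisons, although both W1 libraries stood apart together. In the main fits the difference between W1 and W2 thus counts as spread between replicates. Their 0 calls for matrix over both genotypes depend on this choice.

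The 34 gene list tests and their alternatives (an estimated correlation, fry, the block, libraries left out, another scaling) were not run, because the IDs carry no names. Depth limits only low-count IDs: the smallest library held 30632355 counts.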

Other observations

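The tests of the W1 libraries, the count of splits for genotype, the counts of large differences and gaps, the pairings of splits, the splits that part every number and the exchange of libraries were chosen only after the result was seen; the tests of cell cycle genes and of the matrix splits were set beforehand. As a view of proliferation that needs no gene names, 48 tested IDs that a mouse cell cycle training set links to the G2 and M phases were followed. Averaged over matrices, 20 were higher and 28 lower in Jak2 V617F than in control cells, with a median log2 fold change of −0.036. The hypothesis that these genes are higher in Jak2 V617F cells was not borne out by camera on the edgeR model (adjusted p = 0.90, and 0.93 with an estimated correlation of 0.045). This result depends on the control number. The mean log2 CPM of the G2 and M IDs was 2.88 (viscous) and 2.89 (elastic) in W2, and 3.10 and 3.09 in W1. In the Jak2 V617F libraries it was 2.97 to 3.08, above both W2 libraries and below both W1 libraries. Between elastic and viscous matrix 21 were higher and 27 lower (median −0.024), and camera gave an adjusted p of 0.90 there too, and 0.93 with an estimated correlation. edgeR called 0 of the 48 in either contrast, with 4 and 5 at unadjusted p under 0.05; limma-voom and DESeq2 also called 0. A small difference is not excluded.

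Among the 11743 IDs with a mean of at least 50 counts, 31 had a log2 fold change between matrices above 1.5 in both genotypes, and 6 had one below −1.5, while 2 went beyond these limits in opposite directions. This lean was not tested and depends on the limit: it was 12 against 0 at 2 log2 units, 67 against 42 at 1, and 210 against 249 at 0.5. Other counts were even or leaned either way. Over both genotypes DESeq2 called 67 higher and 67 lower, and 429 higher and 499 lower IDs had an unadjusted edgeR p under 0.05. Within genotypes DESeq2 called 23 higher and 12 lower in control cells, and 20 and 15 in Jak2 V617F cells. IDs without overlap between the matrices numbered 306 higher and 245 lower. The median log2 CPM of the 31 IDs was 3.78 in W2, 3.81 in J1 and 3.85 in J2 in elastic matrix, but 2.32 in W1. In viscous matrix it was 0.23 in W1, 0.71 in J2 and 1.06 in W2, but 1.91 in J1. W1 in elastic and J1 in viscous matrix thus lay nearest to the other matrix for these IDs, which were picked on the matrix difference after the data were seen.

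The first principal component set the W1 libraries apart within the control cells. Of 14785 IDs, 4575 (30.9%) had both W1 libraries above or both below the other 6, where chance gives 7.14%; the next highest of the 28 pairs of libraries, both W2 libraries, had 2000. Among these, the mean log2 CPM in W1 differed from that in the other 6 by more than 2 for 308 higher and 203 lower IDs. Library depth is argued against, since W1 in viscous and J1 in elastic matrix held 35011427 and 35007587 counts but lay farthest apart of the 28 pairs (1.08 log2 CPM), and W1 in elastic matrix lay at 1.03 from J2 in elastic matrix, the nearest in depth, while no pair outside W1 exceeded 0.786. RNA of another cell type added to W1 alone is argued against by 147 well-counted IDs without overlap whose mean log2 CPM in W1 was lower by more than 2. RNA of a cell type missing from W1 alone is argued against by 224 whose mean was higher by more than 2. A replacement of 1 cell population by another, a difference of culture or animal, and a wrong label stay open; genotype and matrix would set W1 apart from W2 only if a label were wrong, since both carry the same ones.

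The W1 contrast and the matrix response shared IDs, mostly in opposite directions. With each genotype fitted alone in edgeR, 3345 of 13736 IDs had an unadjusted p under 0.05 between W1 and W2, 1141 had one between matrices in Jak2 V617F cells, and 458 had both, where independent lists would share 277.9. In 383 of them the direction of W1 against W2 was opposite to that of elastic against viscous matrix, and in 75 it was the same, against 140.6 and 137.3 by chance. This comparison was found by looking at all 9 pairings of splits. Among these, the share of IDs in the more frequent direction was highest, at 98.9%, for matrix against matrix, and reached 85.5% for number against number, so a one-sided direction alone is not rare in these libraries.

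Over all 35 splits of the 8 libraries into 4 and 4, chance was not excluded for the counts between matrices. In an edgeR model with 2 groups of 4, elastic against viscous gave 2 calls (ENSMUSG00000060586 and an ID that is not named), and 2 of the 35 splits gave as many, the real one included. For IDs whose libraries did not overlap, the real split gave 551 (306 higher and 245 lower in elastic matrix), where chance gives 2.86% of IDs or 422, and 8 of the 35 splits gave as many; the highest other count was 1493. IDs at unadjusted p under 0.05 numbered 880, and 12 of the 35 splits gave as many. Of the 8 splits that place the libraries of every title number on opposite sides, the matrix split had the highest counts (2 calls against 0, and 551 IDs without overlap against at most 462 in the others), but 8 splits are too few for a share under 0.05. For genotype the model gave 1 call (ENSMUSG00000062783), and 6 of the 35 splits gave as many; for its 1953 IDs at unadjusted p under 0.05 and its 1019 IDs without overlap 3 of the 35 splits did so. The highest other split gave 271 calls, against 2 and 1 for the real ones, which points to a structure of the samples. It sets both W1 libraries with W2 and J2 in viscous matrix against W2 and J2 in elastic matrix and both J1 libraries, so it differs from the matrix split by an exchange of W1 in elastic and J1 in viscous matrix. Well-counted IDs with a gap of more than 1 log2 unit between the sides numbered 32 in that split and 5 between the matrices (4 higher and 1 lower in elastic matrix). Other values follow the labels. With W1 in elastic and J1 in viscous matrix exchanged, the genotype split left 429 IDs without overlap, against 1019 as labelled, and W1 in elastic matrix lay closer to W1 in viscous matrix (0.77 log2 CPM) than to any other library (0.967 or more). The named IDs also follow the labels in both libraries, but were chosen under them. Reads that cover the mutation, which would test an exchange directly, are not used here.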
